A study of Mus musculus with 4 samples.

How the data were processed

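The study measured RNA in single cells of mouse skin with the 10x Genomics Chromium 3′ v3.1 chemistry in 4 libraries, 1 each for untreated skin, oxazolone day 10, oxazolone day 16 and MC903 day 9. Each library pooled cells of 3 mice, so mice within a library could not be told apart. Per the labels, neck and ear skin was digested with an enzyme mix containing collagenase and dead cells were removed before loading. The deposited matrices hold raw UMI counts (unit: counts) per gene and barcode, with 32285 genes in every library, and the barcodes had already been called as cells by the authors, with a smallest total of about 500 UMIs. The submitters' processing notes name Cell Ranger 8.0 and the mm10 genome for all libraries, whereas the file headers name version 7.2.0 for the untreated and oxazolone day 10 libraries and 8.0.0 for the MC903 and oxazolone day 16 libraries. The annotation, the use of intronic reads and further filters are not given in the sources used here. Library totals ranged from 73054242 to 119717836 UMIs.

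The following choices, the gene lists and the rule for named genes were made before the data were examined, apart from those named as chosen later. Cells with at least 300 genes and at most 15% mitochondrial UMIs were taken, which left out 53, 407, 290 and 342 barcodes (untreated, oxazolone day 10, oxazolone day 16, MC903). Doublets were scored with Scrublet as built into scanpy, per library, and the cells with the highest scores were removed at a rate of 0.8% per 1000 barcodes, which took 475, 495, 501 and 132 cells. The 26152 kept cells were scaled to 10000 UMIs, log transformed and reduced to 2000 variable genes and 30 principal components, without integration between libraries. A graph of 15 neighbours, weighted by shared neighbours, was clustered with the Leiden algorithm at resolution 1. Clusters in which a share of at least 0.5 of the cells held a UMI of Ptprc, the pan-leukocyte gene, were clustered again, and a cluster with both mast cell and basophil markers a further time, which gave 53 clusters, numbered from 0 within the rounds A, B and C. A cluster took the name of 1 of 28 marker sets when at least 3 of its markers were each seen in 20% of cells, their mean log2 ratio to the average cluster was at least 1 and no unrelated set came within 0.5. Clusters whose 10 leading genes held more markers of another class, or few UMIs and none of their own markers, stayed unnamed. The thresholds for naming and the weighting by shared neighbours were not among the choices fixed beforehand. This left 6 unnamed clusters and 19 named classes, called by their name with the ending "-like", since no protein was measured.

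Within a class and library, UMIs were summed over cells and scaled to the same total in every class and library (CPM, the usual scale for counts). Ratios were computed for 5 pairs of libraries (each treated library against untreated skin, oxazolone day 16 against day 10, and MC903 against oxazolone day 10) where both had at least 50 cells of the class. A count of 0 was set to a floor of 3 UMIs, and such a ratio is a bound. Of 28 gene lists, members with at least 30 UMIs in the pair of libraries count as measured, and a member is called higher or lower at a ratio of at least 2-fold. A list's median log2 ratio stands beside its percentile among 10000 random lists of the same size drawn from 20 bins of mean expression, as a description of these libraries and not as a test. The interval of a list median comes from 2000 Poisson redraws of its counts. Named genes follow a fixed rule: per list and comparison at most the 4 measured members with the largest absolute log2 ratio; in fibroblast-like cells the 8 highest and 8 lowest ratios over untreated skin, and in keratinocyte-like and macrophage-like cells the 5 highest and lowest, among genes with at least 200 UMIs in the higher library; and, in every library, Il4, Il13, Il4ra, Il13ra1, Tslp, Il33, Ccl11, Mcpt8, Cyp24a1 and the 15 source and 8 receptor genes. Mitochondrial, ribosomal, hemoglobin, immunoglobulin, predicted and sex-linked marker genes were left out of the highest and lowest ratios. Results that need an item withheld for evaluation are not reported here. The symbol lists use the names of the gene table, with Lor or Loricrin and Ccn2 or Ctgf taken as found. Receptor shares count cells with a UMI after each cell was thinned at random to 1000 UMIs. As a measure of RNA from other cells, the 6 neutrophil markers were compared between each class and neutrophil-like cells of the same library. It differed between classes: with MC903 its median was 1.47% in fibroblast-like, 0.116% in chondrocyte-like and 10.1% in lymphatic endothelial-like cells. It is therefore not a measure of free RNA alone, and how the RNA came into these cells was not tested. The level of a gene in a class was also set against that in the highest named class with at least 10 cells.

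The ratio and list steps were tested on simulated data, a comparison of 15217 genes. They had the mean profile of the whole untreated and oxazolone day 10 libraries, at fixed fractions of the library totals. These fractions gave fewer UMIs than the fibroblast-like cells of those libraries held. For genes without a difference the median absolute log2 error was 0.10, 96.4% of intervals held the true ratio and 0.950% reached 2-fold. Of genes made 2-fold, 4-fold and 8-fold higher or lower, 94.4%, 97.0% and 95.2% of intervals held the true ratio. The 2-fold limit was reached in the true direction by 45.1%, 100% and 100% of them. Of 500 lists of 10 unchanged genes, 2% reached the percentile that all lists of 2-fold higher genes reached. The simulation holds no variation between mice or preparations, which these libraries cannot show either.

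Alternatives changed one choice at a time: the cell filter (at least 200 genes and at most 25%, or 500 and 10%), no doublet removal, resolutions 0.5 and 2, basophil-like cells as those with at least 2 Mcpt8 UMIs, fibroblast-like cells as those with at least 3 of 6 markers, scaling by the median ratio of genes with at least 50 UMIs, the mean over cells, 5% of the class total taken off as free RNA, 10 or 100 UMIs for a measured gene, 10 bins, all barcodes, and no thinning or thinning to 500 UMIs. Chosen after seeing the data were cluster A9 alone (where a library held at least 40 of its cells), list members at 5% or more of their level in the highest class, and shares without neutrophil-like cells and cluster B11. Gene positions are those of GENCODE M21 on GRCm38 (mm10), counted from 1, in which 32158 of the 32285 gene identifiers were found. The analysis ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.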

Results

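Transcripts of single skin cells were counted in 4 libraries, 1 per group, each pooled from the neck and ear skin of 3 mice. Mice of the reference group were left untreated. No vehicle-treated library was analysed here, so effects of the vehicle cannot be told from those of oxazolone or MC903. Oxazolone, a contact hapten that gives an allergic skin reaction in sensitised mice, was applied at 3% for sensitisation and at 1.0% for challenges that began 7 days later, and skin was taken on day 10 or day 16. MC903 (calcipotriol), a vitamin D analog used to give mice a dermatitis, was applied at 1 nmol in 100 µL, and skin was taken on day 9. The title of the series names an axis of basophils and fibroblasts in type 2 skin inflammation. The comparisons ask which cell classes each library held, which classes held type 2 cytokine transcripts and their receptors, and how expression within a class differed between libraries. The untreated, oxazolone day 10, oxazolone day 16 and MC903 libraries held 7755, 8708, 8199 and 4185 barcodes with 92861164, 119717836, 108142462 and 73054242 UMIs. After filtering, 7227, 7806, 7408 and 3711 cells were kept in that order, with a median of 10133, 11146, 8826 and 14371 UMIs per cell. With 1 library per group there was no spread between replicates, so no difference between groups was tested, and every difference below has no replicate check. The 95% intervals are exact (Clopper-Pearson for shares, Poisson for counts, conditional binomial for ratios) and cover counting error only.

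Neutrophil-like and macrophage-like cells were much more frequent after oxazolone than in untreated skin, while fibroblast-like and keratinocyte-like cells took smaller shares of the library. Neutrophil-like cells were 5 of 7227 untreated cells (0.0692%), 18.7% at oxazolone day 10, 56.9% at day 16 and 7.92% with MC903. These shares leave out the unnamed cluster B11, whose closest marker set was that of neutrophils but which had hemoglobin genes among its leading genes. It held 18 untreated cells (0.249%), 336 at day 10 (4.30%), 28 at day 16 (0.378%) and 3 with MC903 (0.0808%). Macrophage-like or monocyte-like cells made up 1.85% of untreated cells and 24.8%, 20.3% and 5.07% of the treated libraries in the same order. Basophil-like cells, named from the protease genes Mcpt8 and Prss34 among others, numbered 11 of 7227 untreated cells (0.152%, interval 0.0760 to 0.272). They numbered 83 at oxazolone day 10 (1.06%, 6.99 times the untreated share, interval 3.71 to 14.5), 56 at day 16 (0.756%, 4.97 times, 2.57 to 10.5) and 66 with MC903 (1.78%, 11.7 times, 6.12 to 24.5). Of the named immune cells alone they made up 0.664% in untreated skin, 1.93% at day 10, 0.896% at day 16 and 7.18% with MC903. Fibroblast-like cells were 24.0% of the untreated library (1734 cells), 5.16% at oxazolone day 10 (403), 4.63% at day 16 (343) and 29.9% with MC903 (1111). Keratinocyte-like cells were 24.2%, 12.6%, 1.17% and 2.83% in the same order, and chondrocyte-like cells 12.4%, 6.39%, 2.17% and 17.5%. Of the chondrocyte-like clusters, A12 had Col2a1 and Acan among its leading genes, whereas A5 had 0 chondrocyte markers among its 10 leading genes. Cluster A5 held 53.2% of the untreated and 96.8% of the MC903 cells of the class. The amounts of neck and ear skin in each pool, on which the chondrocyte-like share may depend, are not given in the sources used here. Alpha beta T-like cells stood at 1.09% in untreated skin and 4.18%, 2.61% and 4.18% in the treated libraries. Gamma delta T-like cells made up 9.48% against 0.705%, 2.17% and 2.83%, and ILC2-like cells, innate lymphocytes that make IL-5 and IL-13, 0.955% against 0.167%, 0.0540% and 0.539%. Unnamed clusters held 5.73%, 14.0%, 4.54% and 7.68% of the kept cells. Because shares add up to a whole, a large class lowers all others: counted without neutrophil-like cells and the unnamed cluster B11, a setting chosen after seeing the data, the fibroblast-like share at oxazolone day 16 was 10.8% and the basophil-like share 1.77%. Counted instead as cells with at least 3 of 6 fibroblast markers, fibroblast-like cells made up 47.8%, 21.1%, 14.4% and 53.3%, and with at least 2 Mcpt8 UMIs the untreated basophil-like share was 0.0692%, while the untreated neutrophil-like share reached 0.304% at resolution 0.5. What enzymatic digestion, dead cell removal and the depth of each library add to these shares was not tested, and each share rests on 1 library.

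**Figure D1:**
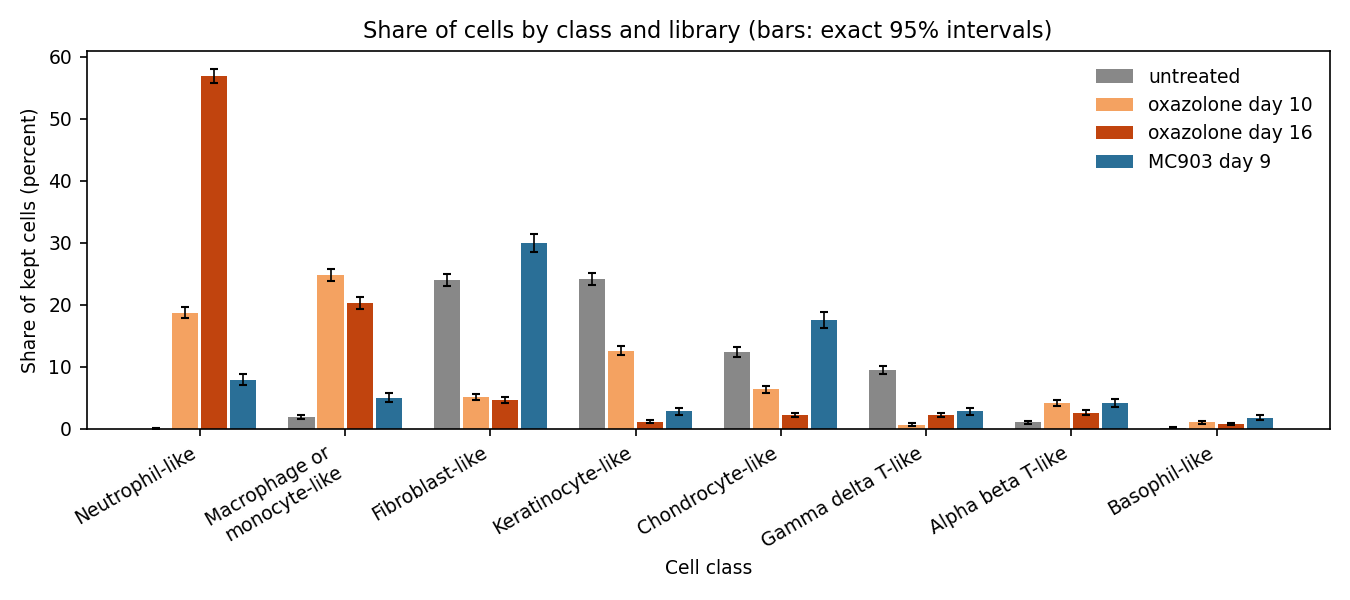
Share of kept cells (percent, y axis) in 8 classes (x axis) in each library, with bars for the share and error bars for the exact 95% binomial interval. The neutrophil-like bar reaches 56.9% at oxazolone day 16 against 0.0692% in the untreated library.

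Most Il4 transcripts in every treated library lay in basophil-like cells. Il4, the cytokine that starts and keeps type 2 responses, had 72 UMIs in untreated cells, of which basophil-like cells held 14 (19.4%, interval 11.1 to 30.5), mast-like cells 21 and ILC2-like cells 16. The basophil-like share was 75.4% of 293 UMIs at oxazolone day 10 (interval 70.1 to 80.2), 94.0% of 3959 at day 16 (93.2 to 94.7) and 87.5% of 3788 with MC903 (86.4 to 88.5), from classes that made up 1.06%, 0.756% and 1.78% of the cells. Alpha beta T-like cells held 37, 53 and 186 Il4 UMIs in those libraries and none in untreated skin with the clustering used, but at resolution 0.5 their log2 ratio of MC903 over untreated was -0.73. Il13, which acts on epithelium and fibroblasts, had 100 UMIs in untreated skin, 55% of them in gamma delta T-like cells and 27% in ILC2-like cells. In the treated libraries basophil-like cells held 61.8% of 34 Il13 UMIs (day 10), 82.6% of 258 (day 16) and 85.8% of 597 (MC903). Il5, the eosinophil growth factor, was mostly an untreated transcript: 161 UMIs, 94.4% of them in ILC2-like cells, against 7, 1 and 10 UMIs in the treated libraries. Since Il5 is in the marker set by which the ILC2-like class was named, its share there is in part given by the naming. Il3 had 29 UMIs at oxazolone day 16, all in basophil-like cells, and 0, 1 and 6 in the untreated, day 10 and MC903 libraries, where basophil-like cells held none. Il31, an itch cytokine, was close to absent, with 3 UMIs at oxazolone day 10, 2 at day 16 and none elsewhere.

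**Figure D2:**
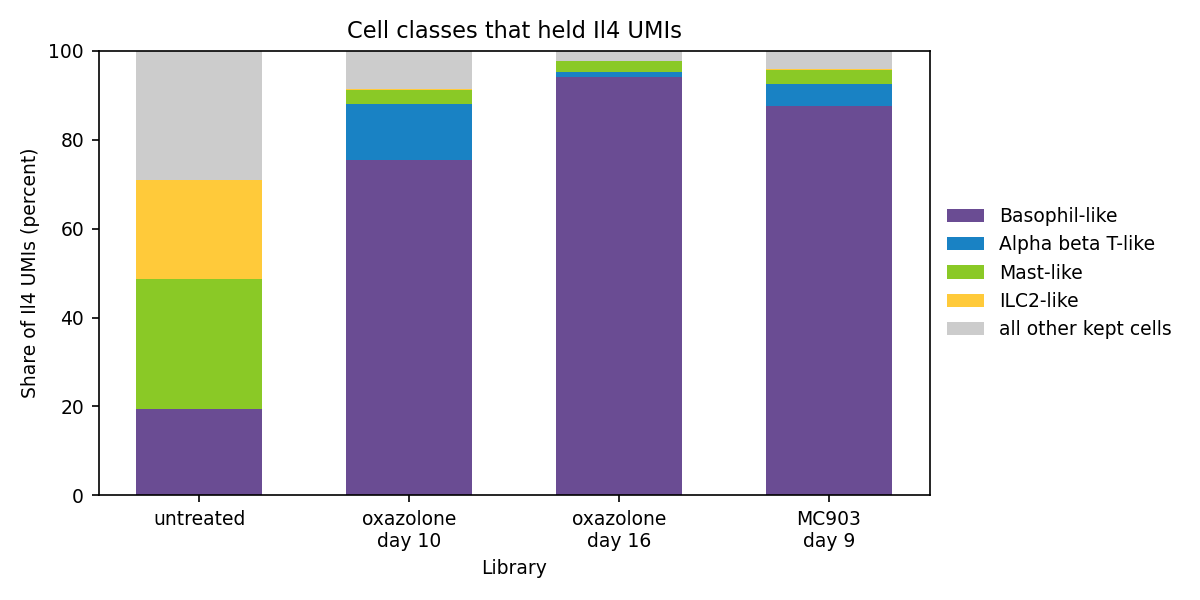
Share of a library's Il4 UMIs (percent, y axis) held by each class (stacked colours) in the 4 libraries (x axis). Basophil-like cells hold 19.4% of the untreated UMIs and 75.4%, 94.0% and 87.5% at oxazolone day 10, day 16 and with MC903.

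Fibroblast-like cells were the main holders of the alarmin Il33 after treatment. In untreated skin 60.0% of 918 Il33 UMIs lay in keratinocyte-like cells and 35.1% in fibroblast-like cells, whereas fibroblast-like cells held 95.9% of 2284 at oxazolone day 10, 95.4% of 4327 at day 16 and 95.4% of 1516 with MC903. Tslp, an epithelial alarmin known to be induced by MC903, had 246 UMIs with MC903 (59.3% in fibroblast-like cells) against 99 in untreated skin, 72 at oxazolone day 10 and 79 at day 16. Relative to the class total, Tslp with MC903 stood at 4.99 CPM in fibroblast-like and 17.1 CPM in lymphatic endothelial-like cells. Most UMIs of Ccl11, the eosinophil and basophil attractant eotaxin, lay in fibroblast-like cells: 94.8%, 78.0%, 94.1% and 90.3% in the untreated, day 10, day 16 and MC903 libraries. Relative to the class total, mural-like cells came close to fibroblast-like cells at day 10 (74.1 against 82.6 CPM) and with MC903 (210 against 223 CPM). At day 16 they stood lower (110 against 262 CPM). Ccl24, a related eotaxin, lay in macrophage-like or monocyte-like cells (98.0% of 195364 UMIs at day 16, 96.9% of 254 in untreated skin). Ccl22, a T cell attractant, lay in dendritic-like cells (98.7%, 97.2%, 98.2% and 97.5%), and so did most Ccl17 (94.1%, 62.1%, 63.8% and 80.7%). Ccl22 is itself in the mature dendritic cell marker set, so its share there is in part given by the naming. The monocyte attractant Ccl2 lay mostly in fibroblast-like cells of untreated skin (56.9%) and in macrophage-like or monocyte-like cells after oxazolone (61.9% and 90.8%) and MC903 (61.8%). Ccl7 and Ccl8 followed this division, with fibroblast-like shares of 77.0% and 65.7% in untreated skin and 8.97% and 2.35% at day 16. Such shares depend on class size as well as on the level in a class. Within fibroblast-like cells Ccl2, Ccl7 and Ccl8 had log2 ratios over untreated skin of 2.98, 2.63 and 1.37 at day 16. These were 1.03, -0.14 and 1.79 at day 10 and -0.057, 0.14 and -1.40 with MC903. Osm, a cytokine of the IL-6 family, had 202 UMIs in untreated skin, 4830 at oxazolone day 10 and 28551 at day 16, where neutrophil-like cells held 60.5% and 64.7%, and 4700 with MC903, where macrophage-like or monocyte-like cells held 45.2% and basophil-like cells 21.7%.

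Basophil-like cells also held more cytokine transcripts at oxazolone day 16 and with MC903 than at oxazolone day 10. Of 12 measured members of the basophil and mast cell effector list, 9 were at least 2-fold higher at day 16 than at day 10 and 0 lower (median log2 ratio 2.49, percentile 100 among 10000 random lists matched on expression, a description of these libraries). Areg, an epidermal growth factor ligand, had a log2 ratio of 7.08, interval 6.10 to 8.30, Il4 of 4.29 (8863 against 453 CPM), Il13 of 3.56 and Il6 of 3.20. With MC903, 9 of 12 members were higher than at oxazolone day 10 and 0 lower (median 2.27), led by Il13 (4.17), Il4 (3.46), the chemokine Ccl4 (3.39) and Areg (3.16). Csf2, which encodes GM-CSF, was at least 239-fold higher at day 16 and at least 41.0-fold higher with MC903, against 0 UMIs at day 10. A UMI of Il4 was found in 60.2% of 83 basophil-like cells at oxazolone day 10, 83.9% of 56 at day 16 and 81.8% of 66 with MC903, at median depths of 5924, 8024 and 8772 UMIs. The 5 cells with the most Il4 held 59.7%, 56.9% and 51.5% of the class's Il4 UMIs, and the median cell had 157, 2156 and 529.9 Il4 CPM. The 9 measured NF-kB targets had a median of 0.84 at day 16 (4 higher, 0 lower), the 12 measured with MC903 one of 1.28 (8 higher, 0 lower), and the dissociation stress genes, known to respond to tissue digestion, 0.63 and 1.52. With the 11 untreated cells below the minimum of 50, no ratio against untreated skin is given for this class. The median of all genes lay at -0.26 (day 16) and -0.28 (MC903) against day 10, and the ratios above are relative to the class total. The file header of day 10 names Cell Ranger 7.2.0 and those of day 16 and MC903 name 8.0.0. These ratios therefore also run between versions, which was looked at only for Il4 at day 16.

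Il4ra, the receptor chain shared by IL-4 and IL-13, was found in a larger share of macrophage-like or monocyte-like cells than of fibroblast-like cells in every library, and in few keratinocyte-like cells. With every cell thinned to 1000 UMIs, Il4ra had a UMI in 4.25% of fibroblast-like cells in untreated skin (interval 3.35 to 5.32), 7.25% at oxazolone day 10 (4.91 to 10.2), 7.51% at day 16 (4.92 to 10.9) and 3.39% with MC903 (2.39 to 4.67). These shares left out 17, 3, 10 and 50 shallower cells, and without thinning they were 32.7%, 57.6%, 64.4% and 41.7%. Summed over the class, Il4ra stood at 41.3, 109, 115 and 39.0 CPM. Macrophage-like or monocyte-like cells had thinned Il4ra shares of 7.87%, 14.5%, 24.8% and 18.7%, and keratinocyte-like cells 0.583%, 0.920%, 2.33% and 0%. Neutrophil-like cells had 15.7%, 6.64% and 5.80% in the treated libraries. Melanocyte-like cells, taken as a class without the gene, had none among 214, 68, 13 and 57 thinned cells, at median depths of 3414, 13838, 28044 and 9217 UMIs against 12817, 27829, 36051 and 24290 in fibroblast-like cells before thinning. Il13ra1, the partner chain for IL-13, lay in 6.93%, 7.50%, 9.91% and 8.29% of fibroblast-like cells, and the decoy receptor Il13ra2 in 0.582%, 2.50%, 4.50% and 0.283%. Osmr, the oncostatin M receptor, lay in 9.55%, 9.50%, 16.2% and 15.7% of fibroblast-like cells and 6.22%, 12.9%, 14.5% and 25.2% of chondrocyte-like cells. Il1rl1, the IL-33 receptor, lay in 72.7%, 37.5%, 37.7% and 65.6% of basophil-like cells and 0.0582%, 7.50%, 4.20% and 0.0943% of fibroblast-like cells. Ccr2, the receptor that draws monocytes into tissue and a gene of the monocyte marker set, lay in 29.9%, 38.5%, 21.9% and 17.1% of macrophage-like or monocyte-like cells. The TSLP receptor chain Crlf2 lay in 15%, 5.66% and 12.5% of basophil-like cells of the treated libraries, and the eotaxin receptor Ccr3 in 1.25%, 0% and 1.56%. Melanocyte-like cells of untreated skin had 0% for Il13ra1, 1.40% for Osmr, 0% for Il1rl1 and 0.467% for Ccr2.

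**Figure D3:**
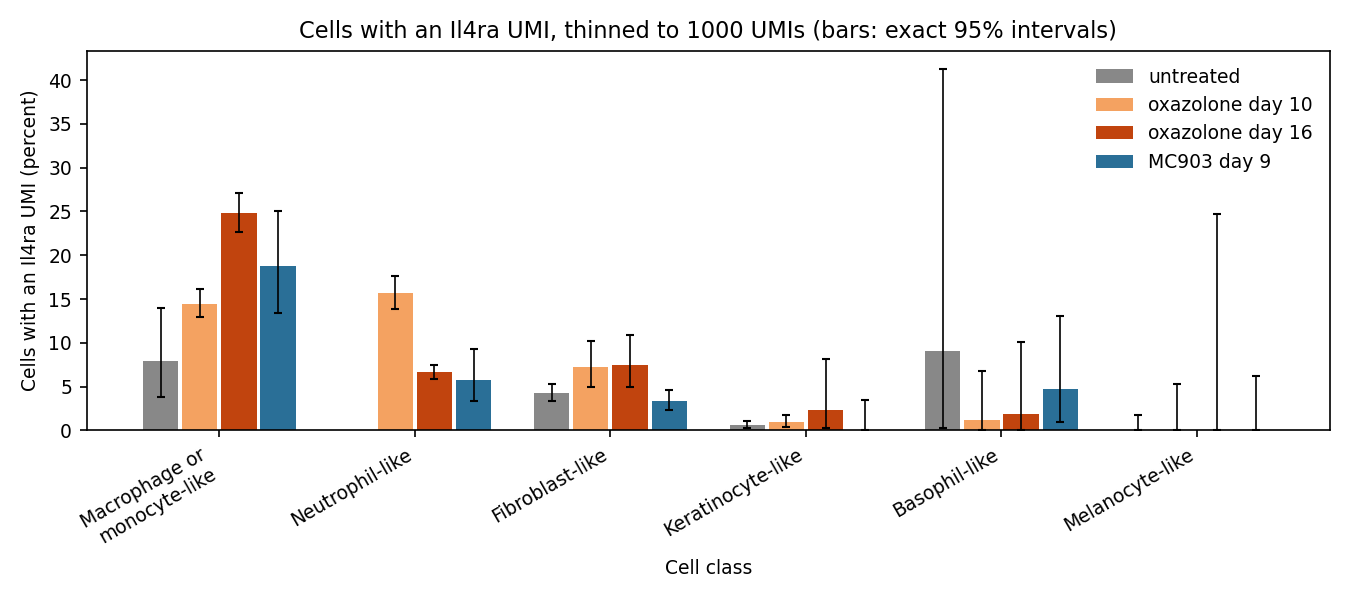
Share of cells with an Il4ra UMI after thinning to 1000 UMIs (percent, y axis) in 6 classes (x axis) and 4 libraries (colours), with exact 95% binomial intervals; classes with fewer than 10 thinned cells in a library are not drawn. Macrophage-like or monocyte-like cells reach 24.8% and fibroblast-like cells 7.51% at oxazolone day 16.

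At oxazolone day 10, fibroblast-like cells held far more transcripts of inflammatory chemokines, cytokines and cell cycle genes than in untreated skin, and more of contractile genes. Of 19 measured members of the chemokine and cytokine list, 12 were at least 2-fold higher, 1 lower and 6 in between (median log2 ratio 1.73, interval 1.60 to 1.82, percentile 100), and the median was 1.04 with 5% of the class total taken off as free RNA. Cxcl5, which attracts neutrophils, stood at 1636 against 0.343 CPM (log2 ratio 12.22, interval 11.24 to 13.43), Il33 at 189 against 13.8 CPM (3.77) and Il11, a profibrotic cytokine, at 39.2 against 1.50 CPM (4.71). Csf3, the neutrophil growth factor G-CSF, was at least 79.0-fold higher, with no UMI in untreated cells. Among 14 NF-kB targets only 3 were higher and 1 was lower: the acute phase genes Saa3 (1399 against 0.300 CPM) and Lcn2 (96.5 against 0.214 CPM) and the mitochondrial dismutase Sod2 (2.43) against the adhesion molecule Icam1 (-1.13). Il4ra (1.40, interval 1.27 to 1.52) and Il13ra2 (3.29) were higher among the 4 type 2 cytokine receptors, with Il13ra1 at 0.35, and Il1rl1 (5.87) and Il1r1 (1.43) led the 13 other cytokine receptors (3 higher, 2 lower). The IL-4 and IL-13 response list had 4 higher and 2 lower of 8 (median 0.62, interval 0.40 to 0.88), with Ccl11 at -1.22. Cell cycle genes were higher in 14 of 15 (median 4.81), among them Top2a (5.65) and Cdk1 (5.53). Neutrophil markers stood in these cells at 0.0884 to 0.424% of their level in neutrophil-like cells, a measure of RNA from other cells. The median higher member of the chemokine list stood at 188% of its level in the highest other class.

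Some matrix genes known from wounds, and most contractile genes of the list, were higher in fibroblast-like cells at oxazolone day 10. Of 21 collagen and matrix genes 4 were higher and 1 was lower (median 0.39, interval 0.34 to 0.41): tenascin C, Tnc (3.61), Col12a1 (3.15) and the crosslinking enzyme Lox (1.81) were higher, and the basement membrane collagen Col15a1 (-1.20) was lower. The metalloprotease inhibitor Timp1 (1388 against 37.2 CPM, log2 ratio 5.22) and the protease Mmp3 (1.75) were higher and the inhibitor Timp3 (-1.72) lower among 10 protease genes (4 higher, 2 lower). The myofibroblast list had 7 of 8 members higher (median 1.99), including Lrrc15 (2.19), while Acta2 (2.96), Tagln (2.39) and Cnn1 (3.81) stood at 3.07%, 2.78% and 2.21% of their level in mural-like cells. Markers of papillary fibroblasts went both ways (2 higher, 3 lower of 7), with Crabp1 (4.11) and Col23a1 (2.98) higher and the Wnt pathway genes Apcdd1 (-2.40) and Axin2 (-2.26) lower, though less so within A9 (-1.01 and -0.70). Adventitial markers were lower in 3 of 7, Dpp4 (-2.58) most. The complement gene Cfb (1.39) was higher, glycolysis genes such as Pkm (1.83) and Ldha (1.42) were higher in 5 of 12, and interferon response genes in 4 of 12 (median 0.57, within cluster A9 -0.55). The interferon gamma list had 3 higher and 1 lower of 13, with the chemokine Cxcl9 at 6.05 and Irf1 at -1.48. Dissociation stress genes were lower in 9 of 12 (median -1.40), with Atf3 at -2.35. MHC class II (0 higher, 0 lower of 6) stayed between the limits, and the adipogenic list had 2 higher, led by Fabp4 (4.57, at 2.72% of its level in blood endothelial-like cells), and 1 lower, Apoe (-1.86).

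By the rule for the 8 highest ratios, Cxcl5, Saa3, Lcn2, the haptoglobin gene Hp (log2 ratio 10.15, interval 8.60 to 12.43, 1702 against 3 UMIs), Tnfsf11, which encodes RANKL (8.29), the antimicrobial lectin Reg3g (7.99), Reg1 (at least 392-fold higher) and the vesicle gene Rab3c (at least 183-fold higher) led at oxazolone day 10. The lowest ratios, among them Cdh4 (-5.64), Ntng1 (-5.59) and Zfp536 (-5.02), include 1 leading gene of cluster A17, Cdh4, and this cluster held 646 untreated cells and none of any treated library. Of the 403 day 10 cells, 71.5% lay in cluster A9, led by Cxcl5, Saa3 and Tnc, and of the untreated cells 37.3% lay in A17, 34.8% in A15, led by Postn, Cilp and Col1a1, and 20.9% in A9. Within A9 alone, a setting chosen after seeing the data, Cxcl5 was at least 3489-fold and Saa3 at least 2766-fold higher at day 10, Il33 had a log2 ratio of 2.13 and Il1rl1 of 4.24, and the chemokine list had a median of 1.38.

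By oxazolone day 16 the chemokine and cytokine list of fibroblast-like cells stood higher still over untreated skin. The NF-kB list, with a median of -0.24 at day 10, was at 0.97. The chemokine and cytokine list had 17 of 19 members higher and 0 lower (median log2 ratio 2.98, interval 2.89 to 3.06, percentile 100). Cxcl5 stood at 1609.6 against 0.343 CPM (log2 ratio 12.20, interval 11.22 to 13.41), the B cell attractant Cxcl13 at 4.95 and Il33 at 4.57. Tslp was at 1.05, and within A9 at -0.017 (interval -0.88 to 0.90). Csf3 was at least 309-fold higher, and Cxcl2 (6.15) stood at 2.52% of its level in neutrophil-like cells. NF-kB targets were higher in 6 of 14, including Saa3 (2839 against 0.300 CPM, log2 ratio 13.21), Sod2 (2.52) and Cebpb (1.42). The IL-4 and IL-13 response list had 6 of 10 higher and 1 lower (median 1.48, interval 1.27 to 1.71), with Ccl11 at 0.44; its median was 0.45 with 5% of the class total taken off as free RNA and 0.83 within cluster A9. Il4ra (1.48, interval 1.37 to 1.60), Il13ra2 (3.34) and Il13ra1 (0.49) stood close to their day 10 ratios, with Il4ra at 0.83 within A9. Other cytokine receptors were higher in 6 of 13, among them Il1rl1 (4.88, at 2.86% of its mast-like level, and 3.05 within A9), Il1r1 (1.83), the shared signalling chain Il6st (1.50) and Crlf2 (1.08). Interferon response genes were higher in 9 of 12 (median 1.77, but 0.42 within A9), such as Isg15 (2.29), Bst2 (2.21) and Irf7 (2.05), and interferon gamma response genes in 7 of 13 (median 1.47), such as Cxcl9 (5.64), Gbp4 (4.01) and Cxcl10 (2.46). Cell cycle genes were higher in 14 of 15 (median 4.60), with Top2a at 6.17 and Cdk1 at 5.31. Neutrophil markers stood at 1.16 to 1.61% of their neutrophil-like level, more than at day 10, and 2 of the 17 higher chemokine members stood under 5% of the highest other class. Lists of other cell types were higher too: the alternatively activated macrophage list in 4 of 6 (median 3.84, within A9 6.02) and the basophil and mast cell effector list in 6 of 8 (median 3.89, within A9 3.99). With 5% free RNA taken off, too few macrophage members were left for a median, and the effector median was -0.17, reversed.

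Matrix genes at oxazolone day 16 were mixed over untreated skin: 4 of 21 were higher and 1 lower (median 0.19, interval 0.15 to 0.21), again with Tnc (3.11), Col12a1 (2.12) and Lox (1.95) against Col15a1 (-1.60); within A9 the median was -0.031. Protease genes had 6 higher and 2 lower of 11, with Timp1 at 5.68 and Mmp3 at 2.62. The myofibroblast list had 2 of 7 higher (median 0.64, within A9 1.25), Cthrc1 (1.21) among them, and the papillary list 5 of 7 lower, with Apcdd1 (-4.79), Axin2 (-3.78) and the Wnt inhibitor Dkk2 (-3.55) lower and Crabp1 (2.40) higher. Within A9 Apcdd1 was at -1.61, Axin2 at -1.47 and Dkk2 just under 2-fold lower, and the papillary list had a median of -0.90. Complement genes Cfb (1.59) and C4b (1.28) were higher. Glycolysis and hypoxia genes were higher in 6 of 12, such as Eno1 (1.68) and Hk2 (1.64), and the lipid genes held lipoprotein lipase, Lpl (2.12), higher and Apoe (-2.40) lower. Adventitial markers (0 higher, 0 lower of 7) and MHC class II genes (0 and 0 of 6) showed few or no members past 2-fold, and dissociation stress genes 1 of 12 lower, Atf3 (-1.50). The highest single ratios were those of Saa3, Cxcl5, Hp (10.06, interval 8.51 to 12.34, 1734 against 3 UMIs), Lcn2 (9.43), Reg1 (at least 630.2-fold higher) and the chemokine Cxcl3 (at least 571-fold higher), with the phagocyte genes Clec4e and Slfn4 at 1.72% and 1.95% of their level in the highest class. Cluster A9 held 84.5% of the 343 day 16 cells, and within A9 alone the chemokine list had a median of 2.92, Cxcl5 was at least 2983-fold higher and Il33 had a log2 ratio of 2.69. The median of all genes lay at -0.12 on the log2 scale in this pair, and the ratios are relative to the class total.

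Fibroblast-like cells of the MC903 library had another profile: the vitamin D target Cyp24a1 and lipid genes were higher, most collagen and matrix genes of the list and most MHC class II genes lower, and the chemokine list was only modestly higher. Cyp24a1, the vitamin D degrading enzyme, stood at 2185 against 0 UMIs, at least 580.2-fold higher, and 4 of the 5 measured vitamin D receptor targets were higher (median log2 ratio 2.80), a list that was also higher at oxazolone day 10 (1.81) and day 16 (2.84). The chemokine and cytokine list had 9 of 19 higher and 3 lower (median 0.64, interval 0.58 to 0.70, percentile 99.7), with Cxcl5 (53.6 against 0.343 CPM, log2 ratio 7.29), Cxcl13 (6.32), Il33 (1.84) and Tslp (1.77, interval 1.23 to 2.36) higher. Csf3 was at least 11.9-fold higher, at 1.14% of its level in blood endothelial-like cells. NF-kB targets were higher in 6 of 14, led by Saa3 (9.17), Sod2 (1.67) and Cebpd (1.37). The IL-4 and IL-13 response list had 3 higher and 2 lower of 10 (median 0.063, interval -0.0072 to 0.13, and -0.48 with free RNA taken off), Ccl11 was at 0.21, and the type 2 receptors were near the untreated level (Il4ra -0.082, interval -0.21 to 0.043, Il13ra1 0.31). Osmr (1.02) and Lifr (1.45), receptors of the IL-6 family, were the 2 members higher of 13 other cytokine receptors. Collagen and matrix genes were lower in 12 of 21 and higher in 2 (median -1.01): Col15a1 (-3.30), Col5a3 (-1.93) and Col1a1 (-1.50) were lower and Lox (2.76) higher. Within cluster A9 alone, a setting chosen after seeing the data that left 49 MC903 cells, this list's median turned to 0.40, with Col1a1 at 0.90. The chemokine list had a median of 2.17 there. Tslp was at -0.68 in A9, on 4 against 17 UMIs (interval -2.71 to 0.94), too few to tell a direction. MHC class II genes were lower in 5 of 6 (median -2.35, within A9 -0.47), and adventitial markers in 5 of 7, such as the complement shield Cd55 (-2.65), Cd248 (-2.06) and Pi16 (-1.76).

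Lipid and complement genes were also higher with MC903 than in untreated fibroblast-like cells. The adipogenic and lipid list had 6 of 10 members higher (median 1.99, but 0.065 within A9), including the desaturase Scd1 (2.88) and Lpl (2.44), with Fabp4 (4.77) at 1.44% of its level in adipocyte-like cells. Complement genes that were higher included C4b (2.12), C3 (1.62) and Cfd (3.76, interval 2.13 to 6.08, 51 against 3 UMIs), the last at 0.00931% of its level in adipocyte-like cells. Protease genes had 5 higher of 10, such as Timp1 (2.50, within A9 4.69), the aggrecanase Adamts4 (2.11) and Mmp2 (1.08), and cell cycle genes 7 of 15 (median 0.96, within A9 4.34). Interferon genes were split (1 higher, 2 lower of 12 in the interferon list, 1 and 2 of 13 in the interferon gamma list), and Ifit1 was at -1.74. The myofibroblast list had 2 of 7 lower (median -0.19, within A9 2.75), Lrrc15 (-1.12) among them, the papillary list 2 higher and 1 lower of 7 (Col23a1 2.32, Apcdd1 -1.14, within A9 -0.22), the hypoxia list 1 of 12 higher (Bnip3 1.55) and the dissociation stress list a median of 0.39. Among the highest single ratios, Cyp24a1, Saa3 and the synapse organiser Cbln1 (at least 489-fold higher) stood highest in fibroblast-like cells, whereas Clec4e, Acod1 and Retnlg, genes of neutrophils and macrophages, stood at 1.35%, 1.79% and 1.07% of their level in the highest class. Among the lowest, the keratins Krt5 (-5.22), Krt14 (-4.38) and Krt15 (-8.91, interval -14.21 to -6.42) came from an untreated level of 0.601%, 0.725% and 0.635% of that in keratinocyte-like cells. Of the 1111 MC903 cells 93.3% lay in cluster A7, led by Cxcl13, Inmt and Apod, against 4.09% of the untreated cells, so this profile is that of 1 cluster in 1 library, and within A9 Scd1 was at -0.63 and Lrrc15 at 2.75. Neutrophil markers stood at 1.07 to 1.62% of their neutrophil-like level. The basophil and mast cell effector list was higher in 6 of 9 and lower in 0 (median 4.06, within A9 1.67, and 4.33 with free RNA taken off). The 5% taken off follows the mean profile of the library, in which neutrophil-like cells held 2189175 of 68648032 kept UMIs. It therefore takes off little of their RNA, and the median of 4.33 does not exclude free RNA.

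**Figure D4:**
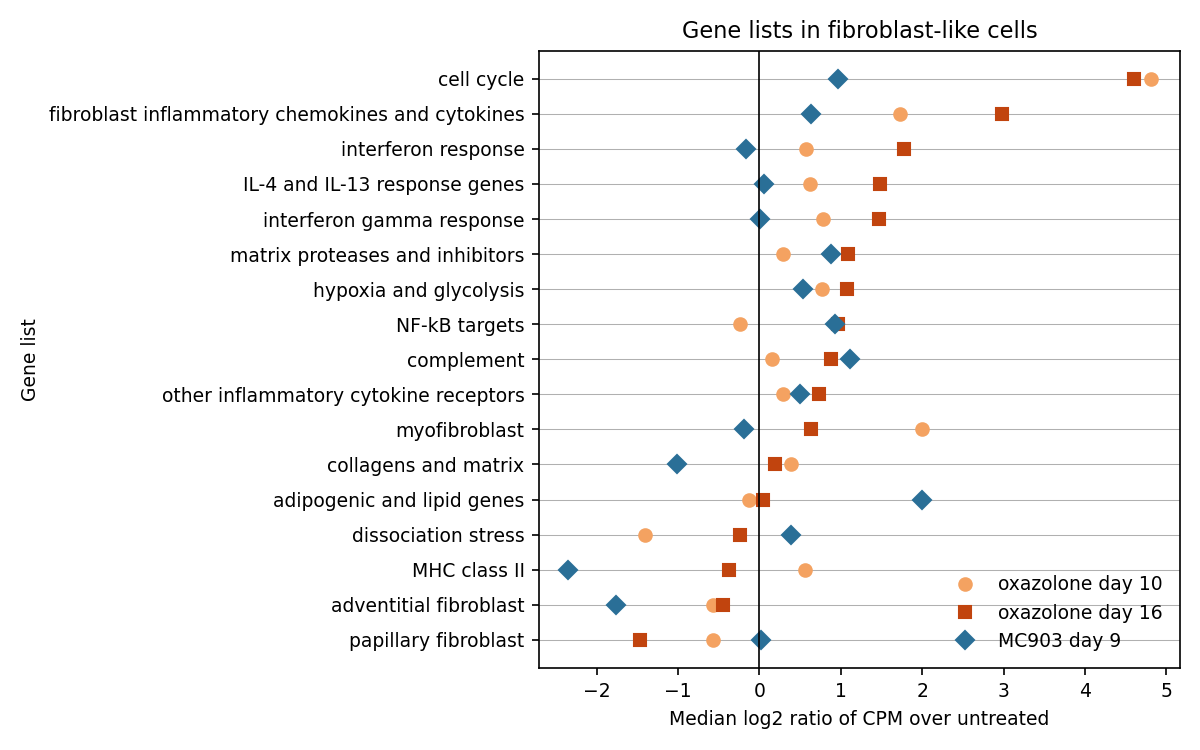
Median log2 ratio of CPM over untreated skin (x axis) of the 17 gene lists with at least 6 measured members (y axis) in fibroblast-like cells, with 1 point per treated library. The chemokine and cytokine list lies at 1.73, 2.98 and 0.64 and the collagen and matrix list at 0.39, 0.19 and -1.01 for oxazolone day 10, day 16 and MC903.

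Between the oxazolone time points, fibroblast-like cells at day 16 held more chemokine, interferon, stress and NF-kB transcripts and fewer contractile and papillary ones than at day 10. The chemokine and cytokine list had 12 of 19 higher and 1 lower (median 1.11, percentile 100), such as Cxcl13 (3.08, interval 2.95 to 3.22), Ccl7 (2.77) and Il6 (2.54). The IL-4 and IL-13 response list had 5 of 9 higher (median 1.24), with Ccl11 at 1.67, the interferon list 7 of 12 (Usp18 1.66, Oasl2 1.37, Irf7 1.25) and NF-kB targets 6 of 14 (Tnfaip3 2.06, Nfkb1 1.78). Complement C3 (1.49) and C4b (1.12) and the adventitial markers Anxa3 (1.96) and Dpp4 (1.94) were higher. The myofibroblast list was lower in 4 of 8, with Lrrc15 at -1.55, the papillary list in 5 of 7, and Col12a1 (-1.03) alone of 21 matrix genes. Il4ra was at 0.088, interval -0.022 to 0.20 and the cell cycle list at -0.15, both within 2-fold of the day 10 level. Dissociation stress genes were higher in 8 of 12 (median 1.30) and moved with these groups. Neutrophil markers in these cells reached 0.424% of their neutrophil-like level at day 10 and 1.61% at day 16. The IL-4 and IL-13 response median at day 16 over untreated skin fell to 0.45 with 5% free RNA taken off. File headers name Cell Ranger 7.2.0 for day 10 and 8.0.0 for day 16, and what this adds in this class was not tested.

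MC903 and oxazolone day 10 fibroblast-like cells differed in matrix, contractile, MHC class II and cell cycle genes over the whole class, differences that were smaller or turned within the cluster they share. Over the whole class, MC903 cells had collagen and matrix genes lower in 16 of 21 (median -1.41; Tnc -2.78, Col3a1 -2.28, Postn -2.13), the myofibroblast list in 7 of 8 (Lrrc15 -3.31), the cell cycle list in 14 of 15 (Mki67 -4.40) and MHC class II genes with a median of -2.48. Type 2 receptors were lower in 3 of 4, with Il4ra at -1.48, interval -1.59 to -1.36 and Il13ra2 at -3.82. The chemokine list divided: 8 of 19 were lower, such as Il11 (-5.92) and Cxcl5 (-4.93), and 5 higher, such as Cxcl13 (4.45), and Tslp was at 1.77, interval 1.04 to 2.59. Il1rl1 (-5.37), Saa3 (-3.02), Timp1 (-2.72), Cxcl9 (-5.46) and Crabp1 (-4.26) were lower, and C3 (2.25), C4b (1.97), Scd1 (3.22), Apoe (1.60) and the Wnt gene Axin2 (2.59) higher. Cyp24a1 was at least 289-fold higher. Dissociation stress genes were higher in 9 of 12 (median 1.86), and most cells of each library lay in different clusters, A7 and A9. The file headers of this pair also name different Cell Ranger versions. Cells of A9 were grouped by likeness of expression, and A9 has Cxcl5, Saa3, Tnc and Timp1 among its leading genes. Smaller or turned values within A9 can follow from this grouping and cannot decide on the whole-class differences. Within A9 alone, with 49 MC903 cells, the collagen list's median was 0.092, the myofibroblast list's 1.18, the chemokine list's 0.42 (whole class -0.65), and Lrrc15 was at 0.10 and Axin2 at -3.13 (1 MC903 UMI, interval -8.47 to -0.58), all turned from the direction in the whole class. Others were smaller there: the cell cycle list had a median of -0.41 (whole class -2.82), MHC class II genes -1.07 and type 2 receptors -0.83 (whole class -1.60), with Il4ra at -0.60, Il1rl1 at -3.05, Cxcl5 at -2.23, Saa3 at -0.56, Timp1 at -0.73 and Scd1 at 0.025.

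Macrophage-like or monocyte-like cells held more transcripts of several alternative activation genes at oxazolone day 16 and with MC903, and fewer of these genes were higher at oxazolone day 10. The IL-4 and IL-13 response list had 7 of 10 members higher than in untreated skin at day 16 (median log2 ratio 2.90), 7 of 9 with MC903 (2.17) and 3 of 10 at day 10 (-0.017). Arginase 1, Arg1, stood at 7072 against 4.45 CPM at day 16 (log2 ratio 10.64, interval 9.41 to 12.26), at 9.31 with MC903 and at 6.31 at day 10. Ccl24 was at 4.79 and 3.38 at day 16 and with MC903 and the chitinase-like Chil3 at 4.00 and 3.92. Il4ra was higher in all 3 comparisons (1.51, 2.48 and 1.94 for day 10, day 16 and MC903). The alternatively activated list went both ways, with 2, 5 and 4 of 10 higher and 5, 3 and 2 lower, Cd209f at -3.96, -3.60 and -4.23, and the lipid regulator Pparg at -2.75, -4.11 and -3.87. Hypoxia and glycolysis genes were higher in 5, 10 and 10 of 12, with Vegfa at 1.76, 4.37 and 4.70. The collagenase Mmp13 (7.43, 6.78) and Timp1 (6.24, 5.32) led the protease list at day 16 and with MC903. Among chemokines, Ccl7 (4.14) and Ccl2 (3.68) were higher at day 16. MHC class II genes were lower at day 16 (6 of 6, median -1.46, H2-Eb1 -2.43) and less so with MC903 (2 of 6), while the interferon gamma list had 7, 5 and 6 of 14 higher, with Cxcl9 at 4.81, 3.74 and 4.34. By the rule for single genes, the arginine carrier Slc7a2 (8.02, 29325 against 4 UMIs) and the activin gene Inhba (9.16, interval 6.68 to 14.47, against 1 UMI) stood among the highest at day 16, and Psd3 (-4.34) and Pmp22 (-3.95) among the lowest. Against oxazolone day 10, day 16 cells held more Arg1 (4.33) and Ccl24 (5.17), with 11 of 15 chemokine and cytokine genes higher and 6 of 6 MHC class II genes lower. MC903 cells against oxazolone day 10 had 4 of 12 hypoxia genes higher (Vegfa 2.95). Clusters differed between libraries: B1, led by Arg1 and Ccl24, held 1084 day 16 cells, 81 MC903 cells and none of the untreated ones, and B6 held 902 of the 1935 day 10 cells. The untreated value rests on 134 cells, and dissociation stress genes had medians of -1.26, -1.15 and -0.41. The median of all genes lay at -0.24 at day 16 against untreated and -0.35 against day 10. Headers of the day 16 and MC903 files name a newer Cell Ranger version than those of untreated skin and day 10. What this adds to the differences in this class was not tested.

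Keratinocyte-like cells held more interferon and wound response transcripts after oxazolone, fewer barrier transcripts at oxazolone day 16 and with MC903, and fewer cell cycle transcripts with MC903. These are sums over a class whose mix of clusters, hair follicle ones included, differed between libraries. Interferon response genes were higher in 9 of 10 at oxazolone day 10 (median log2 ratio 2.13), 9 of 9 at day 16 (2.78) and 3 of 7 with MC903 (0.89). Oasl2 was at 3.44, 4.16 and 3.19 in that order, and Isg15 at 2.63, 3.88 and 1.86, the MC903 values at 3.51% and 1.62% of the neutrophil-like level. Stress keratins and wound genes were higher in 8 of 9 at day 10, 7 of 8 at day 16 and 3 of 7 with MC903, such as the cornifin Sprr1b (5.01, interval 3.1 to 8.09) at day 10 and the defensin Defb14 (5.63) at day 16, while Krt17 was at -1.63 with MC903. S100a8 and S100a9, in the same list, stood at 0.122% and 0.115% of their neutrophil-like level at day 10 and 2.69% and 2.60% at day 16, where the neutrophil genes Retnlg and Cxcr2 stood at 1.90% and 2.21%. Barrier genes went both ways at day 10 (3 higher, 4 lower of 10, median -0.55) and were lower in 5 of 9 at day 16 (-1.29) and 6 of 9 with MC903 (-2.14): Krt2 was at -5.67 at day 10 and, with no UMI, at least 44.7-fold lower at day 16 and at least 68.5-fold lower with MC903. Krt10, a suprabasal keratin, was at -2.51 at day 16 and -2.41 with MC903, and the desmosomal cadherin Dsg1a at -4.11 with MC903, whereas Krt1 was at 1.50 at day 10. Lists of other cell types were higher: the basophil and mast cell effector list in 5 of 7, 8 of 8 and 5 of 8 members (medians 3.00, 4.89 and 4.91) at day 10, day 16 and with MC903, and the alternatively activated macrophage list in 4 of 5 at day 16 (median 6.15). With free RNA taken off the effector medians were 2.29, 5.36 and 5.68, and too few macrophage members were left for a median. The RNA taken off follows the mean profile of the library, so RNA of a class with few UMIs, such as neutrophil-like cells with MC903, is hardly lowered. These medians do not exclude free RNA. Il33 was lower in keratinocyte-like cells in all 3 comparisons (-3.46, -2.50 and -2.98). Cyp24a1 was at least 1830.3-fold higher with MC903 (867 against 0 UMIs). Cell cycle genes had medians of 1.09, 0.0044 and -1.16, with Ube2c at 1.70 at day 10 and -3.52 with MC903. Other single genes at the extremes were the cadherin Cdh6 (8.33) and the stefin Cstdc5 (8.29) at day 10, the steroid enzyme Akr1c18 (-9.43, interval -11.71 to -7.89, 3 against 20180 UMIs) at day 16 and the defensin Defb6 (-8.71) with MC903. The classes held 1746, 986, 87 and 105 cells. Untreated cells lay mostly in clusters A13 (731) and A14 (576) and MC903 cells in A14 (92). Cells of day 10 and day 16 lay mostly in A11 (550 and 64). Cluster A11 had hair follicle (Krt17, Lgr5, Lhx2) and basal markers (Krt5, Krt15) among its leading genes. Cluster A24, named from hair follicle markers, held 0.458%, 29.5%, 23.0% and 1.90% of the untreated, day 10, day 16 and MC903 cells. The ratios are therefore not shown to be changes within a single kind of keratinocyte. What the mix of clusters adds to each ratio was not tested. Dissociation stress genes had medians of -2.13, -0.75 and -1.22, and the median of all genes lay at 0.15 at day 10.

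Gamma delta T-like cells held IL-17 transcripts at oxazolone day 16, and both T cell classes differed between libraries in their mix of clusters. Il17a, which recruits neutrophils through epithelium, was at 546 against 13.0 CPM in gamma delta T-like cells at day 16 (log2 ratio 5.39, interval 4.98 to 5.83) and at -0.14 with MC903, and Il17f was at 2.56, 5.30 and 1.45 at day 10, day 16 and with MC903. Il22 was at 3.38 and 2.20 at day 10 and day 16, and Il2 at -2.34, -4.01 and -1.33, with the epidermal growth factor ligand Areg at -3.16 at day 10 and -1.17 with MC903. Interferon gamma response genes were higher in 6 of 8, 8 of 10 and 5 of 9 members, with Tap1 at 2.14, 2.52 and 1.95. Cell cycle genes were higher in 9 of 11 at day 10, such as Top2a (2.41), in 0 of 12 at day 16 and 5 of 12 with MC903. Cluster B8, with Trdc and Trdv4 among its leading genes, held 91.2% of the untreated cells and 0.621% of the day 16 cells, where B13, with Il17a among its leading genes, held 99.4%. In alpha beta T-like cells Ccl4 was at 3.05, 5.59 and 4.38 at day 10, day 16 and with MC903, at 4.47%, 3.07% and 1.08% of its level in basophil-like cells. Tnf was at -2.73 and -2.58 at day 10 and day 16. The regulatory T cell list had 0, 2 and 2 of 7 members lower, with Foxp3, its master regulator, at -1.43 at day 16 and -1.58 with MC903, and the T helper 2 list 1, 1 and 2 higher and 2, 2 and 1 lower. Cluster B14, with Foxp3 among its leading genes, held 44.3% of the untreated alpha beta T-like cells and 55.8%, 20.7% and 16.8% of those at day 10, day 16 and with MC903, so the Foxp3 ratios go with this mix. Il4 stood at 1.73% of the basophil-like level with MC903. Untreated skin gave 79 alpha beta T-like cells and oxazolone day 10 55 gamma delta T-like cells, and the median of all genes lay at -0.33 (alpha beta) and -0.21 (gamma delta) at day 16 against untreated.

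On the mm10 assembly, Il4 (ENSMUSG00000000869) lies at 53602982 to 53618669 and Il13 (ENSMUSG00000020383) at 53631324 to 53634702 of chromosome 11, where Ccl11 (ENSMUSG00000020676) lies at 82057823 to 82062955. Il4ra (ENSMUSG00000030748) lies at 125552120 to 125579474 and Saa3 (ENSMUSG00000040026) at 46711998 to 46715700 of chromosome 7, and Il13ra1 (ENSMUSG00000017057) at 36112110 to 36171259 of chromosome X. Il33 (ENSMUSG00000024810) lies at 29925114 to 29960718 of chromosome 19, Tslp (ENSMUSG00000024379) at 32815383 to 32819797 of chromosome 18 and Cxcl5 (ENSMUSG00000029371) at 90759360 to 90761624 of chromosome 5. Cyp24a1 (ENSMUSG00000038567) lies at 170482708 to 170497145 of chromosome 2 and Mcpt8 (ENSMUSG00000022157) at 56082166 to 56085273 of chromosome 14. Mcpt8, a basophil protease, stood at 527, 4348, 6872 and 2994 CPM in basophil-like cells of the untreated, day 10, day 16 and MC903 libraries, a gene by which the class was named.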

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

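All tests named in this part were chosen after the result was seen, except the test for a few basophil-like cells with very high Il4 counts. In keratinocyte-like cells, 3 gene lists stood out because their median was at least 1 over untreated skin in one treated library and at most -1 in another; with 1 library per group, the difference was not tested. The cell cycle list was at 1.09 at oxazolone day 10 and -1.16 with MC903. Clusters A24 and A30 had Top2a among their leading genes. In the untreated, day 10 and MC903 libraries A24 held 0.458%, 29.5% and 1.90% of keratinocyte-like cells, and A30 8.30%, 4.97% and 1.90%. What these clusters add to the medians was not tested. Chemokine and cytokine genes were at 1.10 at day 16 and -1.07 with MC903, and the protease list at 1.19 and -1.29. Clusters that no class name covered stood out where the ratio of their share in a treated library to that in the untreated one had an interval above 4. These were A21 (4.84%), A26 (2.38%) and B11 (4.30%) at oxazolone day 10, and A28 with MC903 (1.43%) and at oxazolone day 16 (2.65%). Cluster A21 was led by Mt4, Krt35 and Hoxc13, and A26 by Hhip, Dcc and Rspo2. The closest marker set for A21 was that of hair follicle keratinocytes, with a mean log2 ratio of 0.60, under the limit for naming.

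The chemokine and cytokine list was higher in fibroblast-like cells at both oxazolone time points than in untreated skin. Free RNA from other cells was argued against by the level of the higher members, a median of 188% of the highest other class at day 10 and 75.5% at day 16, where neutrophil markers reached at most 0.424% and 1.61%, although taking 5% off left a day 10 median of 1.04. Another mix of the clusters as drawn was argued against by medians of 1.38 and 2.92 within A9. This cannot decide on cell states inside A9, which was drawn from the same cells and has Cxcl5, Cxcl12 and Il33 among its leading genes. Untreated A9 cells held 0 Cxcl5 UMIs against 18835 at day 10. For day 10, different Cell Ranger versions were argued against by the median of 1.73 between the untreated and day 10 libraries, which share a version. For day 16, the median of 0.64 for MC903 over untreated, whose version is that of day 16, cannot decide. MC903 is another treatment, and 93.3% of its fibroblast-like cells lay in cluster A7. Within A9 its median was 2.17, nearer to the 2.92 of day 16. A mix of cell states within A9 stays open, as does a difference of the 1 untreated pool itself, of handling and of the vehicle. At day 16 the Cell Ranger version stays open too. Also open is the response to oxazolone, which as a hypothesis could give higher chemokine transcripts in these cells and which no replicate tested.

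Il4 was higher in basophil-like cells at oxazolone day 16 than at day 10, at a log2 ratio of 4.29. Different Cell Ranger versions were argued against by Il4 in alpha beta T-like cells of the same libraries, at 0.61 (interval -0.019 to 1.26). A few cells with very high counts were argued against by the ratio of the median cell, 3.78. Dissociation stress stays open as a cause, since the stress list was higher in basophil-like cells as well (median 0.63), though other classes were split, with medians of 1.30, 1.38, 1.10, 1.64 and 0.89 in fibroblast-like, keratinocyte-like, gamma delta T-like, chondrocyte-like and blood endothelial-like cells but 0.16, 0.11, 0.20 and 0.33 in macrophage-like, alpha beta T-like, dendritic-like and neutrophil-like cells. A difference between the time points after oxazolone stays open with it and was not tested.

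Cluster A28, led by the predicted gene Gm10800, held 0, 3, 196 and 53 cells in the untreated, day 10, day 16 and MC903 libraries, with a median of 666, 819.5 and 813 UMIs in the latter 3. Reads of Gm10800 not counted by the older Cell Ranger version were argued against by the day 10 cells, which held 63204 CPM of it under that version. Damaged cells or debris stay open: the nuclear RNA Malat1 stood at no more than 7.53% of its level in other kept cells of the MC903 and day 16 libraries. No biological explanation was tested for this cluster.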

How the results depend on the processing

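No paired analysis was possible because each group had 1 library and no mouse gave cells to more than 1 library; leaving out a replicate was impossible for the same reason. The settings named as cluster A9 alone, members at 5% or more of the highest class, and shares without neutrophil-like cells and cluster B11 were chosen after seeing the data, and all others before. Depth limits what classes with few cells can show: the untreated library held 11 basophil-like and 5 neutrophil-like cells. Of 275 gene ratios of at least 2-fold named in the text, 273 kept direction and 2-fold size under median ratio scaling, 269 with the mean of cells, 273 and 274 with the looser and stricter filters, 271 without doublet removal, and 264 and 273 at resolutions 0.5 and 2. With 5% free RNA taken off, 267 of 269 did, and within cluster A9 130 of 171. Of 67 list medians of at least 1, 67 kept their direction under scaling, the mean of cells, the filters, the doublet setting, the resolutions and the lower UMI minimum. Direction was kept by 66 of 66 at the higher UMI minimum, by 62 of 63 with free RNA taken off, by 53 of 53 with members at 5% or more, and by 32 of 36 in cluster A9. Of the same medians 65 kept 2-fold size under scaling, 63 with the mean of cells, 66 and 67 with the filters, 63 without doublet removal, 66 and 66 at the resolutions, 67 and 64 at the UMI minimums, 57 of 63 with free RNA taken off, 49 of 53 with members at 5% or more and 22 of 36 in A9. All 23 share ratios of at least 2-fold kept their direction under the filters, doublet setting and resolutions. At resolution 0.5, 21 of 23 kept 2-fold size, and in the other settings of these all 23. Without neutrophil-like cells and cluster B11, 19 of 20 did. Values also left their counting interval without turning, apart from the shares and lists at the centre of the text: gene ratios in 47 cases under scaling, 108 with the mean of cells, 22 and 6 with the looser and stricter filters, 60 without doublet removal, 37 and 17 at the resolutions, 31 with free RNA taken off and 133 in A9. For list medians these counts were 32, 57, 18, 5, 45, 22, 15, 33 and 44 in that order, 23 with members at 5% or more and 13 and 17 at the lower and higher UMI minimum. Share ratios did so in 5, 3, 4, 8 and 7 cases with the filters, without doublet removal and at the resolutions, and in 14 without neutrophil-like cells and cluster B11. Cytokine shares did so over all barcodes in 21, and receptor shares in 34 with stronger thinning and 46 without thinning, and 4 percentiles of lists did so with 10 bins.

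The reversed values, and those of the 3 class shares, the Il4 shares and the 3 fibroblast lists at the centre of the text that left their counting interval, follow in the order oxazolone day 10, day 16 and MC903 where groups are not named; the cause was not tested. In cluster A9 alone, whose MC903 ratios rest on 49 cells, the chemokine list had medians of 1.38 at day 10 and 2.17 with MC903, the IL-4 and IL-13 response list 0.83 at day 16 and 0.45 with MC903, and the collagen list 0.18, -0.031 and, reversed, 0.40. Also reversed there with MC903 over untreated were Col1a1 (0.90), Lrrc15 (2.75), Scd1 (-0.63) and Tslp (-0.68, interval -2.71 to 0.94, 4 against 17 UMIs). With day 16 over untreated it was Tslp (-0.017, interval -0.88 to 0.90). Both Tslp intervals span both directions. With MC903 over day 10 the collagen list (0.092), the myofibroblast list (1.18) and the papillary list (-0.94, whole class 1.16) were reversed. So were Axin2 (-3.13, interval -8.47 to -0.58) and Lrrc15 (0.10) in that pair. List medians under 1 in size that had the other sign in A9, with the whole class in brackets, were those of the interferon (-0.55, 0.57), papillary (0.0046, -0.58) and NF-kB lists (0.15, -0.24) at day 10, the collagen (-0.031, 0.19) and dissociation stress lists (0.11, -0.24) at day 16, the myofibroblast (2.75, -0.19), papillary (-0.28, 0.020) and stress lists (-0.12, 0.39) with MC903, and the chemokine list (0.42, -0.65) with MC903 over day 10, among the medians counted above. Free RNA taken off reversed the basophil and mast cell effector median at day 16 (-0.17) and gave chemokine medians of 1.04 and 2.86 for day 10 and day 16 and IL-4 and IL-13 response medians of 0.95, 0.45 and -0.48. Members at 5% or more of the highest class gave chemokine medians of 2.63 and 1.20 for day 16 and MC903 and response medians of 1.00, 0.96 and -0.53. The mean of cells gave chemokine medians of 1.15, 2.58 and 0.57, collagen medians of 0.45, 0.13 and -1.27 and a response median of 0.21 with MC903. Median ratio scaling gave collagen medians of 0.43, 0.32 and -1.04 and a chemokine median of 3.1 at day 16. A minimum of 100 UMIs gave chemokine medians of 3.1 and 0.86 for day 16 and MC903 and a response median of -0.082 with MC903, and 10 UMIs a response median of 0.24 at day 10. Without doublet removal the chemokine medians were 1.55 and 3.16 at day 10 and day 16, the collagen median -0.98 with MC903, the fibroblast-like shares 22.3% untreated and 27.6% with MC903, and the neutrophil-like shares 0.234% untreated, 20.6% and 53.0%. Neutrophil-like shares were 0.248% untreated, 21.9% and 55.3% with the looser filter, 0.240% untreated and 22.9% at day 10 with the stricter one, 0.304% untreated and 23.0% at day 10 at resolution 0.5, and 0.221% untreated, 20.8%, 44.6% and 6.82% at resolution 2. The basophil-like share at day 16 was 1.02% with the looser filter and 1.03% at resolution 0.5, and the untreated one 0.0692% by Mcpt8 UMIs. Fibroblast-like shares by marker UMIs were 47.8% untreated, 21.1%, 14.4% and 53.3%. Without neutrophil-like cells and cluster B11, fibroblast-like cells were 6.70%, 10.8% and 32.5% and basophil-like cells 1.38% at day 10 and 1.77% at day 16. Over all barcodes, basophil-like cells held 68.2% of Il4 UMIs at day 10 and 86.2% with MC903.

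Some of the ratios below were left out of the results after an alternative reversed them, and all stay in the counts above. At resolution 0.5, alpha beta T cells had Ccr8 at 0.048, 0.18 and 0.44 over untreated, where the resolution used had -1.80, -2.16 and -1.69, and with MC903 Il13 at -1.14 against 3.02, interval 0.47 to 8.36 and Il4 at -0.73 against at least 11.2-fold higher. Macrophage Retnla at day 16 was -1.12 with the mean of cells against 3.32, and fibroblast-like Slfn4 with MC903 was -0.17 within A9 against at least 528-fold higher. Keratinocyte S100a8 at day 10, given in the results only as a percent of its neutrophil-like level, was -0.40 with free RNA taken off against 6.75.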

Other observations

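Chondrocyte-like cells, a class outside the comparisons of the results, held more chemokine transcripts at oxazolone day 16 and with MC903 than in untreated skin. Its chemokine and cytokine list had medians of -0.13, 3.54 and 1.14 over untreated skin at day 10, day 16 and with MC903, with 10 of 13 members at least 2-fold higher at day 16. Lif was at 3.92 and the protease Mmp3 at 5.42 at day 16, and Osmr at 0.94, 0.94 and 2.07. MHC class II genes had a median of -1.35 with MC903. The mix of clusters differed, since A5, led by Angptl7 and Mgp, held 96.8% of the MC903 cells and 53.2% of the untreated ones. Cluster A5 had 0 chondrocyte markers among its 10 leading genes, so the MC903 values rest mostly on cells not led by cartilage genes. Genes of other cells were also higher at day 16 (median 7.43 for the alternatively activated macrophage list and 4.54 for the basophil effector list). With MC903 the basophil effector list was higher in 8 of 9 members (median 3.92). Neutrophil markers stood at 2.07 to 2.90% of their neutrophil-like level at day 16 and 0.0448 to 0.295% with MC903. Free RNA is not excluded for these ratios. Dissociation stress genes had medians of -1.87, -0.31 and -0.76 at day 10, day 16 and with MC903. The class held 897, 499, 161 and 650 cells in the untreated, day 10, day 16 and MC903 libraries, and no difference was tested. Day 16 and MC903 also share a newer Cell Ranger version in their file headers than untreated skin and day 10.

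In mural-like cells the chemokine and cytokine list was at -0.42 at oxazolone day 10 and 1.07 with MC903, with Cxcl1 at -2.16 and 1.36, and Cxcl9, with no UMI in untreated skin, was at least 112-fold and 94.6-fold higher. Dissociation stress genes had medians of -2.41 and 0.16 over untreated skin in the same order. With MC903 12 of 12 were higher than at day 10 (median 2.43), so they moved with the chemokine list. At day 16 the class held 47 cells, under the minimum of 50.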
